A study of Mus musculus with 4 samples.

How the data were processed

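Single cells of 2 KPC mouse pancreatic tumors were profiled with 10x Chromium 3' chemistry, per the labels' protocols. Each tumor was digested at 37 C for 45 min, passed through a 100 um strainer and kept at a viability above 75%, per the labels' protocols, and then sorted into an all live and a sorted CAF fraction, giving 4 libraries. The series title gives 2 tumors, the design text gives 2 biological replicates, each in both fractions, and the descriptions of both libraries of a number share a prefix, so libraries that share a number were taken as coming from the same tumor. The design text speaks of 8 samples with technical replicates. All barcodes of the 4 libraries carry the same suffix, 1, so technical replicates could not be told apart here and each library was taken as 1 sample. An EpCAM antibody is not named in the listed stain, which holds one against PDGFRa; the gate is described here as the labels give it.

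The deposited values are UMI counts per gene and barcode, whole numbers with no normalization, which the authors made with Cell Ranger 2.0.0 and CASAVA 1.4 on the genome build mm10, per the submitters' processing notes. The deposited gene and barcode tables that go with the counts hold names only (other text, with no measurement), as deposited by the authors. Gene symbols were taken from the deposited tables, which list 27998 genes with 65 duplicated symbols. How barcodes were chosen before deposit is not given in the sources used here. The 4 libraries hold 8282 barcodes and 85230726 UMIs. Single libraries hold between 14972652 and 30950993 UMIs, with median counts per barcode between 3287 and 13764. With this depth a count of 0 in a class allows up to 3 counts of its total, and 95% intervals (exact Poisson for levels, Clopper-Pearson for shares, the conditional exact interval for odds ratios) cover counting error only.

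Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept, which left 7984. Doublets were called in each library with the scrublet implementation of scanpy 1.11.5 (expected rate 0.05). Its automatic threshold marked 39 cells (0.488%), under the 0.5% below which the fixed rule takes the caller as not having worked, so the cells with the highest doublet scores were left out at 0.8% per 1000 barcodes: 157 cells, leaving 7827. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, with the genes of the tested lists, mitochondrial and ribosomal protein genes left out, gave 30 principal components and a graph of 15 neighbours, and Leiden clustering at resolution 1 with no batch correction gave 27 clusters. A cluster was named for the list with the most markers at least 2 times higher than in other cells and seen in at least 20% of its cells, with a minimum of 3 markers. A cluster also stayed unnamed where as many of its 10 leading genes marked another class as its own, or where its depth was low with no marker among them; 259 cells were in such clusters. The names ending in "-like" rest on these rebuilt clusters and not on an annotation by the authors. Fibroblast-like cells were clustered again at resolution 0.5 with 1000 variable genes and 20 components, separately on each of 2 random sets of genes. The genes of the tested lists were not left out of that step. Genes of one set were tested on the subclasses built from the other, and shares are given for subclasses of the first set.

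Raw counts were summed per library, per library and class, or per tumor and subclass (at least 20 cells a sum), and the sums were the replicates. They were tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr with its default minimum of 10 counts) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment at 0.05. Standard errors are the log2 fold change over the square root of the F statistic, and log2 values of single tumors use a prior count of 2. The comparisons were sorted CAF against all live libraries, fibroblast-like cells of sorted CAF against all live libraries, inflammatory-like against myofibroblast-like fibroblasts, and ligands and receptors across fibroblast-like, ductal epithelial-like and macrophage or monocyte-like cells of the all live libraries. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, and with cameraPR between the subclasses. The 13 tested lists were the IL1 and NF-kB response, JAK-STAT signalling, TGF-beta signalling, collagen and crosslinking, matrix proteases and inhibitors, glycolysis and hypoxia, proliferation, complement, the interferon response, dissociation stress, Hedgehog signalling, the insulin-like growth factor axis, and ligands and receptors. Marker lists of cell types formed a family of their own. Of the list members, Ccl21a, Ighm, Igkc and Leprel1 had no entry under these symbols in the gene tables and were not used here.

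The groups, tests, gene lists, markers, filters, alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names the 12 genes with the highest and the 12 with the lowest log2 fold change among those that passed, with the same direction in both tumors and at least 50 CPM in the higher group. Mitochondrial, ribosomal protein and predicted genes were left out. From lists it names 2 to 4 members with the largest change that passed, and it always gives the gate and stain genes. Of the ligands and receptors it names the 4 largest in each direction of each contrast with at least 20 CPM, and Il1a, Il1b, Il1r1, Tgfb1, Tgfbr2, Il6, Lif, Osm, Hgf and Cxcl1 in any case. Some genes that the rule took are not reported here. The planned fits had no block. Since these called no gene in the first 3 comparisons, the rule was applied to the fits with the tumor as a block in the fibroblast comparisons, a choice made after the calls were seen. Blocked fits of 4 sums leave 1 residual degree of freedom.

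Whether libraries of a number deviate together was checked once: the deviations from the group means correlated at 0.641 over 14228 genes of whole libraries and at 0.552 over 10805 genes of fibroblast-like cells. Libraries shared between 4 and 6 barcodes, and their counts differed by far more than sampling noise (chi-square per degree of freedom 64.3 for the libraries of tumor 1 and 350 for those of tumor 2), so none was taken as a repeat of another. The tests were run on simulated counts with 100 genes changed 4-fold and 100 changed 16-fold. Of the 4-fold genes 53% were recovered for whole libraries (14035 genes), 100% for fibroblast-like cells (8687 genes), 100% for subclasses (10340 genes) and 93% for compartments (11481 genes), with 7, 5, 7 and 11 false calls, and all 16-fold genes were recovered. These are the rates of the fits without a block. In the same order, the blocked fits made 8, 5, 3 and 10 false calls and DESeq2 made 25, 1, 6 and 10. The simulated spread came from the fits with the tumor as a block, and the counts held no difference between tumors. These rates can therefore overstate what the planned fits without a block recover in the real sums.

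The alternatives were the tumor as a block, DESeq2 1.42.0 as the test, its size factors in edgeR, no filter on low counts, a limit of 5% mitochondrial UMIs, doublet calls kept, other clustering resolutions, genes centred within each tumor, another seed, and leaving out each replicate. Further alternatives restricted the fibroblast-like cells to 1 subclass, the subclasses to 1 kind of library, or the depth to that of the smallest sum. Added after the data were seen were the naming of subclusters on over 3 markers, the sums left out in turn in the comparisons of subclasses and compartments, and the block in the list tests.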

Results

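Gene expression was measured in single cells from 2 pancreatic tumors of KPC mice, a genetic model of pancreatic cancer that uses Pdx1-Cre. Each tumor was digested to a cell suspension and sorted into 2 fractions. The all live fraction held every cell that excluded the dye DAPI. The sorted CAF fraction, named for cancer-associated fibroblasts, held live cells that were negative for CD45 (leukocytes), CD31 (endothelium) and EpCAM (epithelium) and positive for podoplanin (PDPN). Libraries 1 came from the first tumor and libraries 2 from the second, so each group had 2 libraries. The all live libraries held 1948 and 3583 barcodes with 30950993 and 14972652 UMIs (transcript molecules counted once each), and the sorted CAF libraries held 1411 and 1340 barcodes with 23067228 and 16239853 UMIs. The median UMI count per barcode was 10744.5 and 3287 in the all live libraries and 13764 and 10083.5 in the sorted ones. Filters left 7827 cells: 1903 and 3329 in the all live libraries, and 1386 and 1209 in the sorted ones.

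The first question was which cells the gate let through. Fibroblast-like cells, which carry collagen genes such as Col1a1 and the proteoglycan gene Dcn, made up 7.36% of all live library 1 (95% interval 6.22 to 8.62) and 12.6% of sorted CAF library 1 (10.9 to 14.5). In tumor 2 they made up 3.45% of the all live library (2.86 to 4.13) and 72.7% of the sorted one (70.1 to 75.2). Ductal epithelial-like cells, defined by keratins such as Krt18, made up 55.3% (53.0 to 57.5) and 76.2% (73.9 to 78.4) of the all live and sorted libraries of tumor 1, and 5.20% (4.47 to 6.01) and 10.6% (8.91 to 12.5) of those of tumor 2. Leukocyte-like cells of all classes together took 27.4% and 81.2% of the all live libraries of tumors 1 and 2, against 0.0722% (1 cell) and 2.98% (36 cells) of the sorted libraries. Most of them were macrophage or monocyte-like, at 25.2% (23.3 to 27.2) and 55.2% (53.5 to 56.9) of the all live libraries. Mesothelial-like cells, whose markers include Msln and Upk3b, made up 6.57% and 10.5% of the all live and sorted libraries of tumor 1, and 10 and 52 cells (4.30%) of those of tumor 2. Pericyte-like cells numbered 20 in all live library 2 and 59 (4.88%) in sorted CAF library 2, against 0 and 4 in the libraries of tumor 1.

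The odds of a fibroblast-like against a ductal epithelial-like cell were 10.3 times as high in the sorted as in the all live library of tumor 2 (95% interval 7.57 to 14.1) and 1.25 times as high in tumor 1 (0.9748 to 1.59), an interval that holds 1. Among cells of at least 10000 UMIs, a limit chosen after the data were seen, they were 18.9 times as high in tumor 2 (10.01 to 37.2) and 0.585 times in tumor 1 (0.307 to 1.08). The odds of a fibroblast-like against a leukocyte-like cell were 574 times as high in tumor 2 (387 to 862) and 651 times in tumor 1 (112 to 25915). These intervals and those of the shares cover counting error only. With 2 libraries per group an exact two-sided permutation test cannot give a p below 0.333, so the shares were not tested. The deposited barcodes had a lowest UMI count of 4972 in all live library 1, 4040 in sorted CAF library 1, 1620 in all live library 2 and 3221 in sorted CAF library 2. Neutrophil-like cells had a median of 2374.5 UMIs in all live library 2 and 6906.5 in all live library 1. In all live library 2, macrophage or monocyte-like (3381 UMIs), dendritic-like (4109), B or plasma-like (2199) and T or NK-like cells (1981) also had medians under the minimum of all live library 1. Whether the minimum changed the shares of these classes was not tested, so leukocyte shares may not compare between the tumors.

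**Figure D1:**
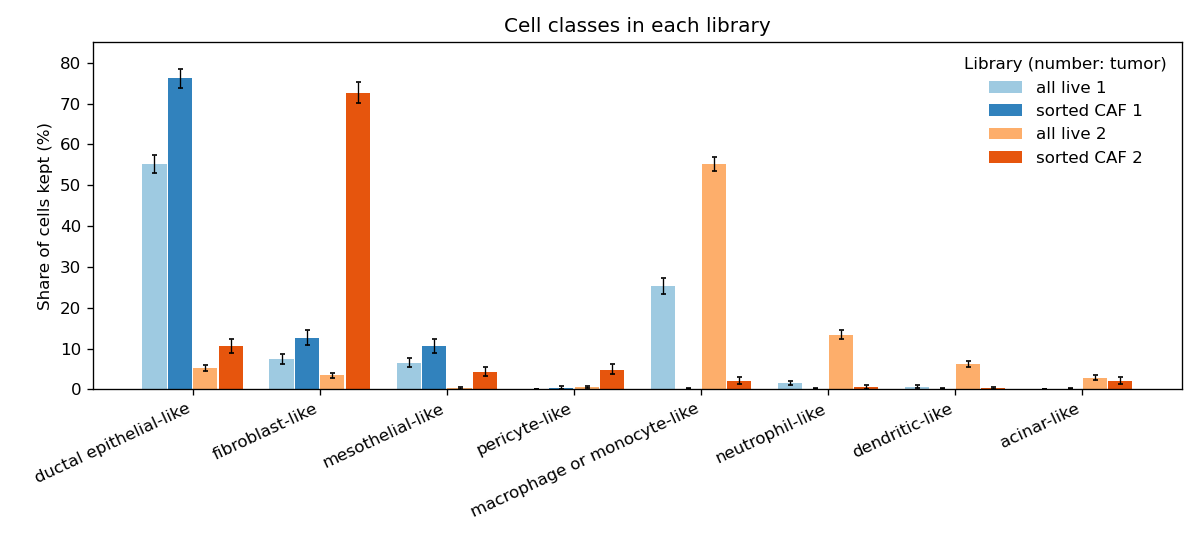
Share of kept cells (%, vertical axis) in 8 cell classes, 1 bar for each of the 4 libraries, with exact 95% binomial intervals as error bars. Fibroblast-like cells stand at 72.7% in sorted CAF library 2 and 12.6% in sorted CAF library 1, where ductal epithelial-like cells stand at 76.2%.

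Ptprc, which encodes CD45, stood at 30.2 and 362 CPM in all live libraries 1 and 2 and at 0.565 and 5.03 CPM in the sorted ones (TMM-scaled levels, log2 fold change -6.14 ± 1.83, SE, n = 2 libraries per group). Epcam stood at 44.9 and 239.5 CPM in the all live libraries and 6.04 and 33.0 CPM in the sorted ones (-2.86 ± 1.23). Pdpn was level in tumor 1, at 39.7 CPM all live and 39.2 CPM sorted, and stood at 32.2 and 209 CPM in tumor 2 (1.79 ± 0.90). Pdgfra, a fibroblast receptor in the stain, went from 15.6 to 19.4 CPM in tumor 1 and from 8.59 to 101 CPM in tumor 2 (2.32 ± 0.95). Pecam1, which encodes CD31, differed by -0.56 ± 0.77, and without all live library 1 by 0.36. None of the 5 genes passed in edgeR's quasi-likelihood test, where the Benjamini-Hochberg adjusted p was 0.99994 for Ptprc, Epcam, Pdpn, Pdgfra and Pecam1 alike.

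Levels within classes are CPM of the UMIs summed over a class, with no further scaling. Within ductal epithelial-like cells, Epcam stood at 56.3 CPM in all live library 1 and 6.85 CPM in sorted CAF library 1, and at 1796 and 169 CPM in those of tumor 2. Pdpn stood at 1.13, 0.550, 6.38 and 11.4 CPM in the same 4 sums, against 310, 385, 301 and 282 CPM in fibroblast-like cells. Vim, the mesenchymal filament gene, stood at 2382 and 2405 CPM in ductal epithelial-like cells of tumor 1, near its 2355 and 2146 CPM in fibroblast-like cells, and at 453 and 1399 CPM in those of tumor 2. Different clusters held most ductal epithelial-like cells of the tumors: cluster 0 was the largest in both libraries of tumor 1 and cluster 9 in both of tumor 2.

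**Figure D2:**
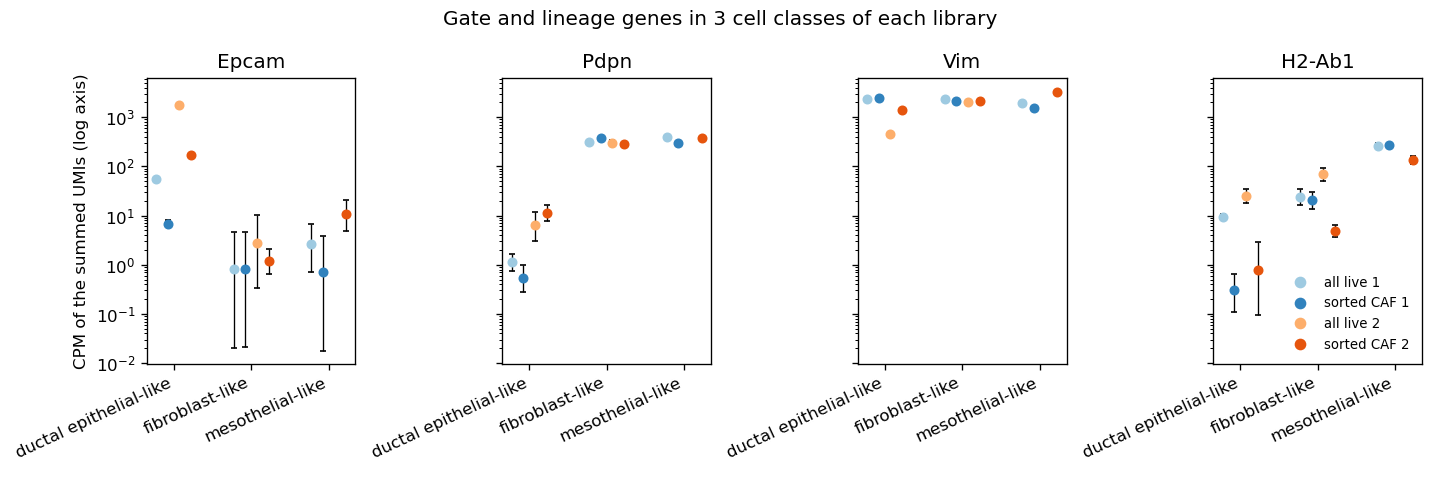
Level of Epcam, Pdpn, Vim and H2-Ab1 in CPM of the summed UMIs (log axis) in ductal epithelial-like, fibroblast-like and mesothelial-like cells, 1 point per library with its 95% Poisson interval; mesothelial-like cells of all live library 2, with 10 cells, are not drawn. Pdpn stands between 282 and 385 CPM in fibroblast-like cells and between 0.550 and 11.4 CPM in ductal epithelial-like cells.

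Over whole libraries no gene passed the planned test. Lyz2, a lysozyme gene of macrophages and neutrophils, stood at 2153 and 8267 CPM in the all live libraries and 2.83 and 133 CPM in the sorted ones (log2 fold change -6.27 ± 2.06). Col1a1 stood at 343 and 354 CPM in the all live libraries and at 424 and 5500.1 CPM in the sorted ones (3.09 ± 1.24). No gene of 14035 passed in edgeR's quasi-likelihood test (536 had an unadjusted p under 0.05), nor with the tumor as a block (992), while DESeq2 called 5 genes higher and 438 lower. The 5 higher genes, named after their values were seen, were Adipoq and Retn, which encode adipocyte hormones, Car3, Pon1 and Mmp3. Adipoq stood at 0.101 and 1.58 CPM in the all live libraries and 5.78 and 65.8 CPM in the sorted ones. An unnamed cluster of 34 cells led by Cfd, Car3, Adipoq and Retn held 0 and 3 cells of the all live libraries and 4 and 27 of the sorted ones.

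Of the cell type marker lists, the 9 macrophage or monocyte genes had a median log2 fold change of -5.74 (limma's camera, adjusted p = 8.39e-20), with 0 passing over all genes and 8 lower when adjusted over the list alone. Medians were -5.15 for neutrophil genes (limma's camera, adjusted p = 3.95e-08), -7.16 for dendritic (2.45e-06), -6.66 for T or NK (2.56e-07), -4.95 for B or plasma (1.25e-10) and -0.83 for blood endothelial genes (7.54e-05). Adjusted over the list alone, 2 dendritic, 3 T or NK, 1 B or plasma, 0 neutrophil and 0 blood endothelial genes were lower. The antigen-presenting fibroblast list, made of class II genes and Slpi, Saa3 and Nkain4, had a median of -5.46 (3.94e-07), with 5 genes lower when adjusted over the list alone and Slpi itself at 0.03. Medians were positive for fibroblast genes (3.02, 5.29e-07), pericyte (2.04, 0.00533), smooth muscle (2.49, 0.00384), mesothelial (1.35, 0.00118), inflammatory fibroblast (2.28, 9.87e-06) and myofibroblast genes (2.54, 8.90e-07), with 0 of their genes passing when adjusted over the list alone. These medians do not separate the tumors. Of the fibroblast list, Col1a1 and Pdgfra rose mainly in tumor 2, and Pdgfra lay between 0.69 and 3.04 over the settings. Ductal epithelial genes (median -0.0049, mean -0.58, 0.0830), acinar genes (-1.89, 0.313) and erythroid genes (median -0.47, test upward, 0.775) did not pass. With the tumor as a block the ductal epithelial and acinar lists passed as lower (limma's camera, adjusted p = 0.0450 and 0.0119; adjusted p = 0.499 and 0.556 with an estimated correlation). Lymphatic endothelial, endocrine, mast and Schwann lists had at most 2 measured genes and were not tested. With an estimated correlation every call on a marker list was lost, the smallest adjusted p being 0.296 without the block and 0.348 with it.

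Of the 13 tested lists, the medians were 2.59 for collagen and crosslinking (23 measured genes, adjusted p = 3.94e-11 by limma's camera), 2.30 for Hedgehog signalling (2.05e-04), 2.14 for matrix proteases and inhibitors (1.49e-05), 1.53 for complement (1.30e-05) and 1.08 for the insulin-like growth factor axis (8.31e-04). TGF-beta signalling had a median of 0.76 (0.0471, and 0.282 with the tumor as a block) and the interferon response -0.35 (0.0479). No member of these lists passed alone, over all genes or adjusted over the list alone. Every call on them was lost with an estimated correlation, the smallest adjusted p being 0.843. Library sums mix all cell classes, whose shares the sort changed. Within fibroblast-like cells the medians were 0.085 for collagen and crosslinking, 0.18 for Hedgehog signalling and 0.19 for matrix proteases and inhibitors. They were 0.14 for complement and 0.10 for the insulin-like growth factor axis there, and none of these lists passed in the planned fit. The IL1 and NF-kB (median 0.08), JAK-STAT (-0.41), glycolysis and hypoxia (0.03), proliferation (-0.03) and dissociation stress (-0.05) lists did not pass, nor did ligands and receptors, with a median of 0.20, a mean of -0.36 and a downward test. In data simulated for this comparison over 14035 genes, the test called 53% of genes changed 4-fold and 100% of those changed 16-fold. The simulated counts held no difference between tumors, so these rates can overstate the power of the planned fit on the real libraries.

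The next comparison asked whether fibroblast-like cells differed between the gated and the ungated suspension of the same tumors. The planned fit without a block called 0 genes. With the tumor as a block, 21 of 8687 genes were higher and 41 lower in the sorted libraries, the lower ones including several neutrophil and macrophage genes. S100a8 and S100a9, which encode the subunits of calprotectin, fell by 5.04 ± 0.25 and 4.18 ± 0.30 on the log2 scale (SE, adjusted p = 4.19e-16 and 4.92e-12 by edgeR). Il1b fell by 5.37 ± 0.36, Tyrobp by 5.21 ± 0.40, Cd74, the class II invariant chain, by 4.83 ± 0.33, Lyz2 by 2.92 ± 0.27 and Cxcl2 by 2.35 ± 0.20. The genes that rose did so less: Hk2, a hexokinase, by 1.28 ± 0.21 (72.7 to 136 CPM in tumor 1, 39.0 to 138 CPM in tumor 2), Igfbp3 by 0.99 ± 0.17, Atp5k by 0.97 ± 0.18, Tnfaip2 by 0.75 ± 0.17 and Malat1 by 0.51 ± 0.13. Cyp26a1, Nudcd3, Tcea3, Lsp1 and Cpxm1 rose as well, and Wfdc17, Cystm1, Arg1, Isg15 and Bhlhe41 fell.

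The fit without the block, which the design named first, called 0 of these genes (63 had an unadjusted p under 0.05), and DESeq2 called 0 higher and 14 lower. Taking the named genes from the blocked fit, which leaves 1 residual degree of freedom, was decided after the calls were seen. Leaving out 1 library moved the count of the fit without the block to 22 genes (all live 1), 53 (all live 2), 63 (sorted CAF 1) and 16 (sorted CAF 2). Without sorted CAF library 1 Igfbp3 turned to -1.28 and Cyp26a1 to -0.77, and without all live library 1 Cystm1 turned to 1.58. The largest share of fibroblast-like cells lay in cluster 10 in tumor 1 (47.9% all live, 58.9% sorted) and in cluster 5 in tumor 2 (66.1% and 63.0%). Pdpn and Pdgfra differed by 0.10 ± 0.30 and 0.18 ± 0.28 between the fractions, and Pecam1 by -0.22 ± 0.70; Epcam and Ptprc had too few counts to be tested.

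Leukocyte genes were lower in the sorted ductal epithelial-like cells too. S100a8 stood at 95.5 and 306 CPM in ductal epithelial-like cells of the all live libraries and at 3.05 and 7.47 CPM in the sorted ones, beside 154 and 185 CPM (all live) and 1.67 and 6.55 CPM (sorted) in fibroblast-like cells. A Lyz2 UMI was seen in 57.4% of ductal epithelial-like cells of all live library 1 (median 19113 UMIs) and 0.663% of those of sorted CAF library 1 (17711.5 UMIs), and in 37.1% and 12.6% of fibroblast-like cells (7121.5 and 6102 UMIs).

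Of the lists fixed for the tumor, the interferon response was lower in sorted fibroblast-like cells (19 measured genes, median -0.37, limma's camera, adjusted p = 1.39e-10; adjusted p = 0.385 with an estimated correlation). In the blocked fit 4 of its genes fell, Isg15 by 1.35 ± 0.19, Ifit1 by 1.37 ± 0.31, Ifit3 by 1.86 ± 0.38 and Ifi27l2a by 0.66 ± 0.15; in the fit without the block 0 passed over all genes and 0 when adjusted over the list alone. The ligand and receptor list passed as lower (47 measured genes, median -0.03, adjusted p = 0.00752; adjusted p = 0.385 with an estimated correlation), with 2 genes lower when adjusted over the list alone, and Il1b, Areg and Cxcl2 lower and Cxcl5 higher in the blocked fit. Matrix proteases and inhibitors passed only with the block (limma's camera, adjusted p = 0.00708, against 0.144 without it), as did ductal epithelial markers (4 measured genes, 4.27e-05 against 0.341), but both calls were lost there with an estimated correlation (limma's camera, adjusted p = 0.726 and 0.442). Krt8 and Krt18 were called lower in the blocked fit, but only tumor 1 showed that direction: Krt8 stood at 263 and 68.4 CPM in all live and sorted fibroblast-like cells of tumor 1 and at 4.23 and 5.43 CPM in those of tumor 2, and Krt18 at 306 and 65.0 CPM and at 0 and 7.67 CPM. Without all live library 1 Krt18 was called higher (log2 fold change 10.05, adjusted p = 0.0445 by edgeR). Neutrophil genes had a median of -4.69 (4 measured genes, adjusted p = 1.76e-67; 0.0249 with an estimated correlation), macrophage or monocyte genes -2.70 (1.30e-28; 0.0506) and the antigen-presenting list -2.11 (3.75e-17; 0.0506). With the block and an estimated correlation none of these 3 lists passed (limma's camera, adjusted p = 0.283, 0.323 and 0.283). Adjusted over the list alone, 3 genes of each of these marker lists were lower. The other 10 tested lists did not pass.

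Fibroblast-like cells were split further with the fixed subclass markers. Inflammatory-like cells made up 72.1% of the fibroblast-like cells of all live library 1 (95% interval 63.9 to 79.4) and 80.0% of those of sorted CAF library 1 (73.3 to 85.7), and 34.8% (26.1 to 44.2) and 33.8% (30.7 to 37.0) of those of tumor 2. Myofibroblast-like cells made up 27.9% (20.6 to 36.1) and 18.9% (13.4 to 25.4) in tumor 1, and 40% (31.0 to 49.6) and 41.5% (38.2 to 44.9) in tumor 2. The rest, 25.2% and 24.7% in the all live and sorted libraries of tumor 2, had under 3 markers of any subclass. No subcluster met the antigen-presenting list at the planned resolution of 0.5. There 0 cells allow a share of up to 2.14% and 2.61% in all live libraries 1 and 2, and 1.71% and 0.341% in sorted CAF libraries 1 and 2. At resolution 0.8 a subcluster met the list with 8 of the 115 fibroblast-like cells of all live library 2 (6.96%, 3.05 to 13.2), and with doublet calls kept the share there was 4.92%. All live library 1 and sorted CAF libraries 1 and 2 held 1 of 140, 0 of 175 and 3 of 879 (0.341%) at resolution 0.8. With doublet calls kept their shares were 2.13%, 0 and 0.226%. Only fibroblast-like cells were split, so mesothelial-like cells, which carried Saa3, Slpi and class II genes of that list, were not counted in these shares. In tumor 1 the inflammatory-like name rested mostly on a subcluster led by Gpnmb and Chchd10 that met 3 markers and held 91 and 125 of the fibroblast-like cells of the all live and sorted libraries. It held 0 and 3 of those of tumor 2. Inflammatory-like cells of tumor 2 came from a subcluster led by Cd55 and Clec3b, with 40 and 294 cells there and 10 and 15 in tumor 1. Without the subclusters that met exactly 3 markers, an alternative chosen after the data were seen, inflammatory-like shares in tumor 1 were 7.14% and 8.57%.

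Inflammatory-like cells had higher levels of genes such as Cxcl13 and Rspo1, and lower levels of genes such as Spp1 and Actg2, than myofibroblast-like cells. Classes came from one random set of genes and tests from the other, and the reverse, so no gene was tested on a class it had helped to cluster. With the tumor as a block, 231 of 10512 genes were higher and 207 lower in inflammatory-like cells (n = 2 tumors). The inflammatory-like sums of the 2 tumors came mostly from different subclusters, so they are not repeats of 1 cell population. Cxcl13, a chemokine that draws B cells, stood at 358 and 686 CPM in inflammatory-like cells of tumors 1 and 2 and at 8.53 and 10.0 CPM in myofibroblast-like cells (log2 fold change 5.86 ± 0.33, adjusted p = 0.00474 by edgeR). Rspo1, a Wnt agonist (4.69 ± 0.33), Tnxb, a tenascin (4.42 ± 0.37), and the scavenger receptor gene Scara5 (3.49 ± 0.31) were higher as well, with Sema3c, Gpnmb, Pamr1, Fmo2 and Ggt5. Spp1, which encodes osteopontin, stood at 189 and 31.7 CPM in inflammatory-like and at 8688 and 1617 CPM in myofibroblast-like cells (-5.59 ± 0.41, adjusted p = 0.00689 by edgeR). Actg2, a smooth muscle actin (-4.42 ± 0.34), Arg1 (-4.53 ± 0.33), Cxcl14 (-4.40 ± 0.87) and Nrep (-3.39 ± 0.51) were lower, as were the mitotic genes Cdc20, Hmmr, Birc5, Cenpa and Cdca3. Clec3b (5.23), C3 (3.45), Tnc (-5.11) and Acta2 (-3.31) also passed, but these genes were among the markers that named the subclasses. Without the subclusters of exactly 3 markers, the mitotic genes Hmmr, Birc5, Cenpa and Cdca3 did not pass (adjusted p between 0.171 and 0.862 by edgeR).

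**Figure D3:**
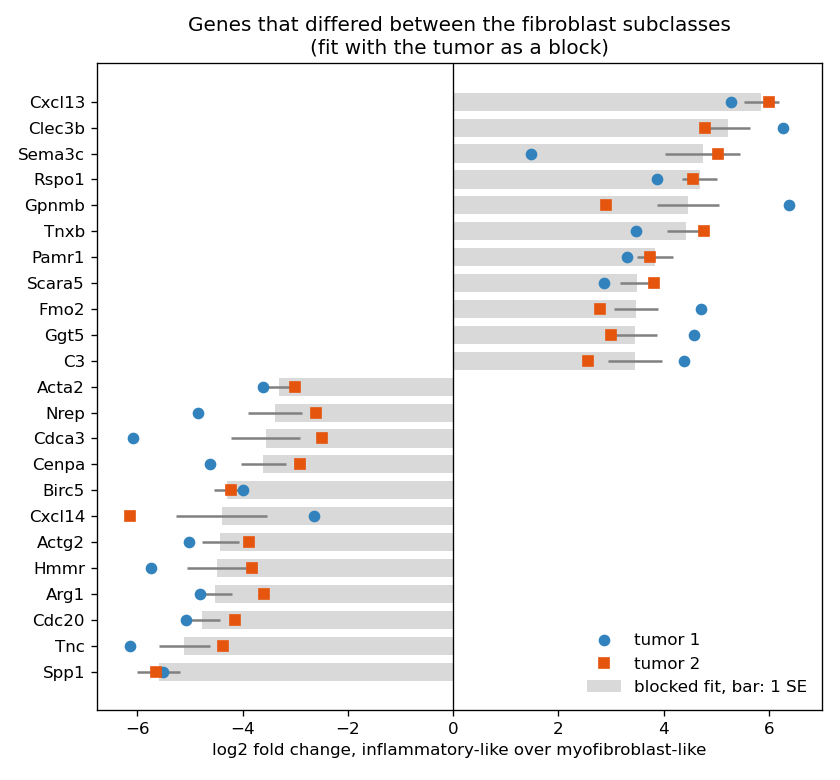
Log2 fold change of inflammatory-like over myofibroblast-like cells for genes named by rule in the fit with the tumor as a block. Bars give the fitted value with 1 SE and points give tumors 1 and 2; Cxcl13 stands at 5.28 and 6.00 and Spp1 at -5.51 and -5.64 in the separate tumors.

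The fit without the block called 0 of the 10512 genes by edgeR (1104 had an unadjusted p under 0.05), and DESeq2 called 136 higher and 127 lower; as above, genes were named from the blocked fit after the calls were seen. Counts moved with the setting, from 0 to 817 genes over the settings tried. Without 1 sum of a tumor and subclass the fit without the block called 127 (inflammatory-like 1), 82 (inflammatory-like 2), 43 (myofibroblast-like 1) and 25 genes (myofibroblast-like 2). The 24 genes that the rule took, each with the same direction in both tumors by selection, kept it in every setting that measured them. Cxcl13, Tnc, Actg2 and Birc5 passed in 13 of 19 settings, against 6 for Spp1, Arg1, Cxcl14, Nrep and Hmmr, 5 for C3, and 4 for Ggt5 and Cdca3. A test of whether the subclass difference itself differed between sorted and all live libraries called 0 of 6268 genes by edgeR (94 had an unadjusted p under 0.05).

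Several of the tested lists stood apart between the subclasses. Proliferation genes had a median of -3.02 over 20 genes (limma's cameraPR, adjusted p = 2.06e-23); 16 were lower when adjusted over the list alone and 12 in the blocked fit over all genes, among them Ccnb1 (-4.82 ± 0.45), Mki67 (-4.49 ± 0.49) and Cenpf (-4.20 ± 0.45). A subcluster led by Cdc20, Hmmr and Birc5 carried exactly 3 myofibroblast markers. Without such subclusters the median was -1.04 (limma's cameraPR, adjusted p = 8.68e-05). In the fit without the block 0 members passed over all genes, with or without them. The tested lists were not left out of the subclass clustering. Members of a list in one random set could thus shape classes on which its members in the other set were tested. Complement genes had a median of 1.42 over 14 genes (1.93e-05), with 6 higher when adjusted over the list alone and 5 in the blocked fit, led by Cd55 (3.45 ± 0.28), C4b (2.62 ± 0.47) and C1s1 (2.30 ± 0.31). JAK-STAT genes had a median of 0.62 (0.00124), with 0 adjusted over the list alone and Myc higher in the blocked fit (1.19 ± 0.23). Dissociation stress genes had a median of 0.97 (4.30e-04), with 2 higher when adjusted over the list alone and Atf3 (2.45 ± 0.23), Zfp36 (1.76 ± 0.24) and Dusp1 (1.72 ± 0.29) higher in the blocked fit. Matrix proteases and inhibitors went both ways (median 0.48, 0.0312), with 7 higher and 3 lower when adjusted over the list alone. In the blocked fit Adamts5 (2.83 ± 0.25), Adamts2 and Adamts1 were higher, and Mmp13 (-3.70 ± 0.71) and Timp1 (-2.93 ± 0.54), an inhibitor of metalloproteinases, were lower. The insulin-like growth factor axis had a median of 0.999 (0.0200) and no member that passed alone. With an estimated correlation these 6 calls held, but only for proliferation was the estimate (0.083) above the preset 0.01. For the other lists it was negative, from -0.093 to -0.021. A negative estimate makes the test less strict, so it is no check of those calls. Without the subclusters of exactly 3 markers the medians were 0.30 for JAK-STAT, 0.80 for complement and 0.51 for insulin-like growth factor genes.

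Glycolysis and hypoxia genes had a median of -1.21 (adjusted p = 1.50e-04; adjusted p = 0.331 with an estimated correlation), with Slc2a1, the glucose transporter, lower (-1.90 ± 0.28) and Adm higher (2.71 ± 0.24) in the blocked fit and 1 gene higher when adjusted over the list alone. Collagen and crosslinking had a median of -0.34 (0.00877; 0.331 with an estimated correlation), with Loxl3 lower (-1.56 ± 0.22), and the interferon response 0.59 (0.00390; 0.452 with an estimated correlation), with Psmb9 higher (2.02 ± 0.35); 0 of either passed when adjusted over the list alone. TGF-beta signalling did not pass (median -0.11, 0.158): Tgfb1 itself (-2.63 ± 0.22), Inhba (-3.15 ± 0.23) and Ltbp2 (-2.66 ± 0.33) were lower and the coreceptor Tgfbr3 higher (2.26 ± 0.23) in the blocked fit, and 1 gene was higher and 3 lower when adjusted over the list alone. The IL1 and NF-kB response did not pass either (median 0.28, 0.118). Its members Il6 and Cxcl1 differed by 0.67 ± 0.36 and 1.22 ± 0.64, Il11 was lower (-1.88 ± 0.37) in the blocked fit, and 0 of 23 passed when adjusted over the list alone. Without the subclusters of exactly 3 markers the medians were -0.22 for collagen and crosslinking, -0.38 for TGF-beta signalling, 0.42 for the IL1 and NF-kB response and -0.039 for Hedgehog signalling. The TGF-beta and the IL1 and NF-kB lists then passed (limma's cameraPR, adjusted p = 0.00602 each), while the matrix protease and insulin-like growth factor lists did not (0.222 and 0.668). Hedgehog signalling (median 0.11, mean -0.01, test upward, 0.798) and the ligand and receptor list (0.28, 0.474) did not pass, with 0 genes, and with 1 higher and 2 lower, when adjusted over the list alone. Pdgfra was higher in inflammatory-like cells in the blocked fit (1.36 ± 0.23), and Pdpn was not called (0.13 ± 0.26).

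The last comparison placed ligands and receptors on the compartments of the all live libraries, where 61 of the 67 fixed genes could be tested among 11481. Against ductal epithelial-like cells, fibroblast-like cells were higher in 19 of them and lower in 7 (23 and 8 adjusted over the list alone; 26 and 8 with the tumor as a block). Igf1 stood at 422 and 1055 CPM in fibroblast-like cells of tumors 1 and 2 and at 0.883 and 1.69 CPM in ductal epithelial-like cells (log2 fold change 9.39 ± 0.77, adjusted p = 8.08e-04 by edgeR). Fgf2 (7.20 ± 0.96), Il6 (7.15 ± 0.88) and the coreceptor Tgfbr3 (6.82 ± 0.61) were higher in fibroblast-like cells as well. Areg, an EGF receptor ligand, was higher in ductal epithelial-like cells (-3.70 ± 0.55), at 235 and 208 CPM against 23.3 and 9.53 CPM. Erbb3, Tgfa and Met, the receptor of Hgf, were higher there too, with 1, 2 and 3 UMIs in fibroblast-like cells, so that the pooled ratios have wide counting intervals: 29.996 for Erbb3 (5.35 to 1188), 17.9 for Tgfa (4.92 to 148) and 7.37 for Met (2.50 to 36.0).

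Against macrophage or monocyte-like cells, fibroblast-like cells were higher in 20 genes and lower in 11 (21 and 12 adjusted over the list alone; 23 and 13 with the block). Fgf7 had 0 UMIs in macrophage or monocyte-like cells and was at least 125-fold higher in fibroblast-like cells, taking 3 counts over the class as the floor. Il33, an alarmin of the IL1 family, stood at 241 and 423 CPM against 2.42 and 1.06 CPM (7.64 ± 0.66, adjusted p = 6.79e-04 by edgeR). Osmr, the oncostatin M receptor, and Wnt5a had 1 UMI each in macrophage or monocyte-like cells, and their pooled ratios were 1012 (179 to 40172) and 296 (50.9 to 11917). Osm itself was higher in macrophage or monocyte-like cells, at 607 and 498 CPM against 6.56 and 19.1 CPM (-5.50 ± 0.64, adjusted p = 0.00144 by edgeR), as were Ccr2 (-6.38 ± 1.07) and Il1a (pooled ratio 44.1, 15.04 to 215). Il1a stood at 152 and 35.8 CPM in macrophage or monocyte-like and at 0 and 4.08 CPM in fibroblast-like cells of tumors 1 and 2. The pooled ratio thus hides a smaller difference in tumor 2 (log2 -3.03, against -8.76 in tumor 1).

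Between macrophage or monocyte-like and ductal epithelial-like cells 18 genes were higher and 16 lower (21 and 19 adjusted over the list alone; 22 and 19 with the block). Ccr2 (7.74 ± 1.12), Il6 (6.72 ± 0.86) and Osm (6.11 ± 0.64) were higher in macrophage or monocyte-like cells. Cxcl5 (-8.72 ± 1.82), Il33 (-6.05 ± 0.62), Erbb3 (-4.45 ± 0.98) and Tgfa (pooled ratio 99.9, 27.5 to 827) were higher in ductal epithelial-like cells.

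Of the genes fixed for naming, Il1b stood at 1497 and 2182 CPM in macrophage or monocyte-like cells of tumors 1 and 2, 29.9 and 96.6 CPM in fibroblast-like and 33.6 and 110 CPM in ductal epithelial-like cells. Between the latter 2 classes the difference was not called (-0.18 ± 0.72), and in the sorted libraries fibroblast-like cells held 0 and 2.62 CPM. Il1r1, the IL1 receptor, was higher in fibroblast-like than in ductal epithelial-like cells (3.24 ± 0.83, adjusted p = 0.0408 by edgeR), at 70.0 and 257 against 13.3 and 21.9 CPM. Tgfbr2 was higher in fibroblast-like than in ductal epithelial-like cells (3.76 ± 0.46) and than in macrophage or monocyte-like cells (1.98 ± 0.43), while Tgfb1 did not pass in any of the 3 contrasts (0.33 ± 0.75, -0.69 ± 0.75 and 1.02 ± 0.75). Between fibroblast-like and macrophage or monocyte-like cells neither Il6 (0.43 ± 0.66) nor Hgf (0.88 ± 0.64) was called; of Hgf ductal epithelial-like cells held 1 UMI. Cxcl1 was higher in fibroblast-like than in ductal epithelial-like cells (2.81 ± 0.60), and Lif, at 4.08 to 9.53 CPM in every class, passed in none. Without the fibroblast-like sum of tumor 1 the calls over the 3 contrasts went from 91 to 56, and without that of tumor 2 to 55. With DESeq2's size factors the median of all genes between fibroblast-like and ductal epithelial-like cells shifted by 0.10, from -0.15 to -0.05.

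**Figure D4:**
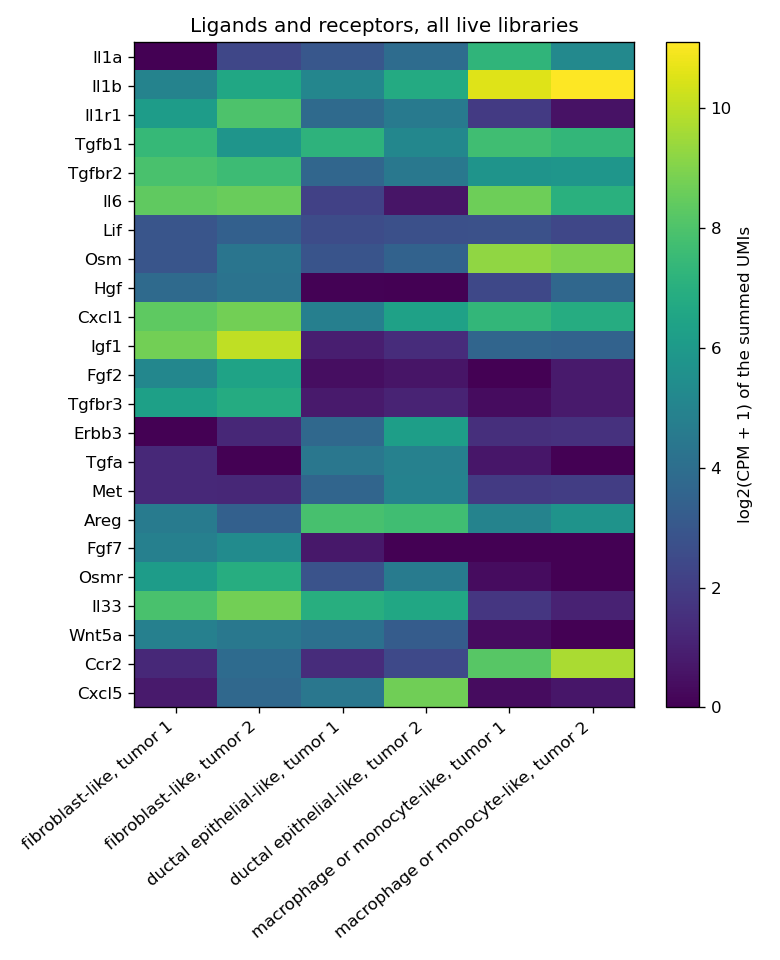
Level of ligands and receptors in the all live libraries, as log2(CPM + 1) of the UMIs summed per class (color scale), with classes and tumors in columns. Among these 3 classes, Il1b and Osm are highest in macrophage or monocyte-like cells, Igf1 in fibroblast-like cells and Areg in ductal epithelial-like cells of both tumors.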

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

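The settings that name subclusters on over 3 markers, leave out 1 sum in the comparisons of subclasses and compartments, or use a block in the list tests were chosen after the data were seen; the others were planned. In 195 checks of a count or a share, values stayed within 1.5 times or within their interval, and in 58 they did not. For named genes, 1124 checks kept direction and side of the threshold, 279 passed where the planned fit had not, 35 no longer passed and 22 changed sign. Where values moved, the cause was not tested, except that leaving out cells, sums or libraries removes data by construction. Resolution 0.5 left the fibroblast-like class unchanged and so tested nothing there.

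With the tumor as a block, the counts of called genes went from 0 to 62 for fibroblast-like cells of sorted against all live libraries and from 0 to 438 between subclasses, to 817 with the block and naming on over 3 markers, and from 91 to 111 for ligands and receptors; whole libraries stayed at 0 in edgeR, with 536 genes at an unadjusted p under 0.05 without the block and 992 with it, while DESeq2 called 443. Without 1 library whole libraries stayed at 0 as well. For fibroblast-like cells, 67 genes were called with no filter on low counts, 14 by DESeq2, 10 with doublet calls kept, and 16 to 63 without 1 library. Between subclasses, 684 were called with no filter, 263 by DESeq2, 170 with naming on over 3 markers, 76 at resolution 0.3, 13 with another seed, 11 at 5% mitochondrial UMIs, 6 with doublet calls kept, 4 at resolution 0.8, 4 in all live libraries only, 1 in sorted CAF libraries only, 1 with 1 clustering on all genes, and 25 to 127 without 1 sum. The only gene called with 1 clustering was Cxcl13, and in sorted CAF libraries only it was Birc5; in all live libraries only Cxcl13, Tnxb, Actg2 and Tnc were called, and at resolution 0.8 Lrg1, Actg2, Birc5 and Cdc20. For ligands and receptors 55 to 106 were called without 1 sum. The number of lists that passed fell to 0 with an estimated correlation for tested and for marker lists over whole libraries and for tested lists in fibroblast-like cells, and to 1 for marker lists there. With the block as well, that marker list no longer passed, the smallest adjusted p of limma's camera being 0.283.

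In all live library 2 the limit of 5% mitochondrial UMIs moved the share of ductal epithelial-like cells to 3.54%, macrophage or monocyte-like to 57.7%, neutrophil-like to 10.1%, dendritic-like to 7.96% and acinar-like to 3.58%, and in sorted CAF library 2 ductal epithelial-like to 8.22%. Macrophage or monocyte-like cells of all live library 2 took 45.5% with doublet calls kept, 49.1% at resolution 0.5 and 48.9% with genes centred within each tumor; neutrophil-like cells took 7.72% at resolution 0.5. In sorted CAF library 2 macrophage or monocyte-like cells took 1.23% with doublet calls kept and 0.993% at resolution 0.5. At resolution 0.8 inflammatory-like shares were 23.5% in all live library 2 and 28.7% in sorted CAF library 2, and myofibroblast-like shares 12% in sorted CAF library 1 and 35.2% in sorted CAF library 2. Antigen-presenting-like shares of all live library 2 went from 0 to 6.96% at resolution 0.8 and to 4.92% with doublet calls kept, and with these kept and classes from the second gene set to 7.38%, beside 2.84% in all live library 1. In sorted CAF library 2 the inflammatory-like share was 42.9% with classes from the second gene set, and the myofibroblast-like share 33.4% at resolution 0.3 and 33.4% with doublet calls kept. With naming on over 3 markers, inflammatory-like shares were 7.14% and 8.57% in all live and sorted CAF library 1, and myofibroblast-like shares 19.3%, 12% and 28.9% in all live library 1 and sorted CAF libraries 1 and 2.

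Signs changed for these log2 differences. Values without 1 library or sum are given as lowest and highest. Pecam1 over whole libraries lay between -1.30 (without sorted CAF library 1) and 0.36 (without all live library 1). In fibroblast-like cells Cyp26a1 lay between -0.77 and 10.75 and Igfbp3 between -1.28 and 3.16 (without sorted CAF library 1 and all live library 1), and Cystm1 between -4.55 and 1.58 (without the same libraries). Pdpn there lay between -0.071 and 0.27 (without sorted CAF libraries 1 and 2) and at -0.21 in myofibroblast-like cells only. Pecam1 there stood at 0.018 with the tumor as a block, between -0.92 (without all live library 2) and 1.75 (without all live library 1), and at 0.25 without sorted CAF library 2. Between fibroblast-like and ductal epithelial-like cells Il1b lay between -1.14 and 0.89, with 0.40 without the fibroblast-like sum of tumor 1, Tgfb1 between -0.76 and 1.76, with -0.28 without the ductal sum of tumor 2, and Osm between -0.17 and 1.21. Il6 between fibroblast-like and macrophage or monocyte-like cells lay between -0.16 and 1.41. Lif between macrophage or monocyte-like and ductal epithelial-like cells stood at 0.093 at 5% mitochondrial UMIs, 0.11 with doublet calls kept and 0.25 at resolution 0.5, and lay between -0.36 and 0.13 without 1 sum. Where an arm was left with 1 sample, it was assumed to vary like the others. Of these genes, Cyp26a1, Igfbp3 and Cystm1 had passed, in the blocked fit.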

Other observations

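All tests of explanations given here were chosen after the result they bear on was seen. Mesothelial-like cells carried high levels of Saa3, an acute phase protein gene, at 7845 CPM in all live library 1, 6202 CPM in sorted CAF library 1 and 4784 CPM in sorted CAF library 2, and of Slpi, a protease inhibitor gene, at 4439, 2825 and 6803 CPM, against at most 471 and 35.0 CPM in fibroblast-like cells. Pecam1 was spread over classes in tumor 1, at 88.3 and 63.3 CPM in ductal epithelial-like and 87.8 and 63.4 CPM in fibroblast-like cells of the all live and sorted libraries, against 11.5 and 17.7 CPM and 12.7 and 29.8 CPM in those of tumor 2. These levels were not tested.

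Most cells of sorted CAF library 1 were ductal epithelial-like. Doublets with fibroblasts are argued against by the fibroblast markers, whose median level in these cells was 0.119% of that in fibroblast-like cells, and an unsorted suspension by leukocyte-like cells at 0.0722% against 27.4% in the all live library. Loss of fibroblasts under the UMI minimum as the reason for the missing enrichment is argued against by cells of at least 10000 UMIs, where the odds of fibroblast-like against ductal epithelial-like cells were 0.585 times those of the all live library (95% interval 0.307 to 1.08; 18.9 in tumor 2, 10.01 to 37.2), though it may have lowered the share itself, since 77.1% of fibroblast-like cells there lay within 2 times of the minimum (76.4% in all live library 1) against 22.3% in sorted CAF library 2. A candidate explanation is that ductal cells low in Epcam passed the negative gate. In tumor 1 the odds of Epcam-rich against other ductal clusters in sorted over all live libraries were 0.117 (0.0301 to 0.332). In tumor 2 they were 0.157 (0.0756 to 0.313). Epcam-rich clusters held 33 cells of all live library 1, against 1019 in other ductal clusters. In sorted CAF library 2 they held 82 against 46, so most ductal cells that passed there were from Epcam-rich clusters. A cluster does not give the Epcam level of its single cells. Over all ductal epithelial-like cells, Epcam was lower in sorted CAF library 2 than in all live library 2, so this count does not speak against the candidate. The odds of mesothelial-like against ductal epithelial-like cells were 1.16 times as high in the sorted library of tumor 1 (0.896 to 1.51). In tumor 2 they were 7.03 times as high (lower limit 3.35). Why cells with little Pdpn RNA passed a positive PDPN gate was not tested, and a biological difference between the tumors stays open.

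Genes that differed between fibroblast-like cells of the sorted and all live libraries in the blocked fit may reflect the suspension. Of the 41 lower genes, 29 were at least 5 times higher in leukocyte-like cells than in sorted fibroblast-like cells. In ductal epithelial-like cells the 29 had medians of -4.99 and -3.40 on the log2 scale in tumors 1 and 2, and 26 moved the same way in both. Free leukocyte RNA in the all live suspension would give this pattern. The rule does not show that leukocytes were the main source of each gene. Areg met it at 38.6 CPM in leukocyte-like cells, though ductal epithelial-like cells of the all live libraries held 235 and 208 CPM. Areg, Cd24a and Ucp2 did not fall in ductal epithelial-like cells of both tumors. The other 12 lower genes had medians of -0.072 and -0.44 in ductal epithelial-like cells. Isg15 (-0.43 and -2.79), Ifit1 (-2.38 and -0.70) and Ifi27l2a (-1.35 and -0.28) fell there in both tumors, and Ifit3 only in tumor 2 (0.20 and -0.70). Pooled levels of these genes and of Bhlhe41 were lower in leukocyte-like than in sorted fibroblast-like cells (Isg15 53.2 and 67.8 CPM, Bhlhe41 4.37 and 33.2 CPM). That argues against free leukocyte RNA for them, while the rest of the 12 stay open. Among the 12 are Krt8 and Krt18, which ductal epithelial-like cells express themselves, so their level there cannot show free ductal RNA. The 21 higher genes had medians of 0.37 and 0.86 in ductal epithelial-like cells, with 13 moving the same way in both tumors, as a change of the whole sorted suspension would give. The median over all genes was not set beside these. Ribosomal protein genes such as Rps28 and Rps29 rose there in both tumors. Of the named genes, Hk2, Atp5k, Nudcd3, Tnfaip2 and Malat1 did so too. Igfbp3 and Lsp1 fell there in both tumors, Tcea3 and Cyp26a1 in tumor 2 and Cpxm1 in tumor 1. In tumor 2 the mix of ductal clusters also differed between the fractions (cluster 1 at 6.36% all live and 25% sorted). Median depth there was higher in the sorted library in both classes, at 5273 and 10627 UMIs in fibroblast-like and 7348 and 16844 in ductal epithelial-like cells. In tumor 1 it was not (7121.5 and 6102, 19113 and 17711.5 UMIs). Whether depth gave part of the agreement between the classes was not tested. A response of fibroblasts alone was not tested.

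MHC class II genes in mesothelial-like cells were the third pattern, with H2-Ab1 at 275 CPM in sorted CAF library 1 and a UMI in 64.4% of these cells against 0.568% of ductal epithelial-like cells (median depths 9248 and 17711.5 UMIs). Free leukocyte RNA is argued against, since the median level over the class II genes in ductal epithelial-like cells was 0.109% of that in mesothelial-like cells. Doublets with macrophages are argued against, since macrophage markers stood at a median of 0.00909% of their level in macrophage or monocyte-like cells, while the median over class II genes was 17.0%. That mesothelial-like cells transcribe class II genes is a hypothesis, found and tested on the same libraries; no biological explanation was tested.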
